A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

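Wild-type cells of the budding yeast Saccharomyces cerevisiae had been exposed to 1.0 mM arsenite, As(III), and total RNA from treated and untreated cells had been hybridised together on 2-colour spotted arrays, per the labels. The series held 15 arrays: 3 after 15 min, 3 after 30 min, 6 after 1 h and 3 after 18 h. Each slide carried treated RNA in one dye and untreated wild-type RNA in the other, so every array had its own untreated measurement. Treated RNA was in Cy5 on 12 arrays and in Cy3 on 1 h replicates 1, 3 and 6. Groups and replicate numbers came from the labels. Growth, treatment, extraction, scanning and normalisation were described there only by reference to a publication and are not given in the sources used here. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels also do not say whether untreated cells were harvested at the same time as treated cells.

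The authors deposited 1 log ratio per spot and array, with no missing value among 13056 spots, and no scanner files were used here. The deposited log2 ratios of 10 arrays were each the log2 of a ratio of 2 whole numbers within the 16-bit range of a scanner (relative tolerance 5e-14, all spots), which natural or log10 logarithms did not give. No brightness-dependent normalisation or centring was visible in those values. Whether a background had been subtracted cannot be told, since subtracting whole numbers would leave such ratios too. On the 3 arrays with treated RNA in Cy3, deposited with fewer digits, 30, 5 and 23 zeros were written with a minus sign, so their signs had been turned before deposit. Their ratios correlated positively with those of the other 1 h arrays (r = 0.722 to 0.883 across genes, which are not independent replicates). From the dyes, these signs and the order of conditions in the titles, all deposited log2 ratios were likely treated over untreated, and that direction is used throughout. The values of 15 min replicate 1 and 30 min replicate 1 were not ratios of whole numbers. How they were made is unknown, and their log2 scale was taken from the other arrays. Their duplicate spots correlated less (r = 0.646 and 0.807) than those of the other 13 arrays (0.871 to 0.990).

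The median log2 ratio over all spots, as deposited, was 2.19, -1.03 and -0.35 for 15 min replicates 1 to 3, and -0.41, -0.39 and 0.01 for 30 min replicates 1 to 3. It was -0.28, -1.19, 0.28, -1.21, -0.59 and 0.09 for 1 h replicates 1 to 6, and -0.10, 1.08 and 0.52 for 18 h replicates 1 to 3. Because these medians lay far from 0, each array was centred on its median over genes, a step set for that case before the data were examined. Every change below is therefore relative to the median gene, and a shift of most transcripts together could not be seen.

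Gene names came from the platform annotation: 11138 spots had 1 gene name, 0 had several, and 1918 had none and were left out of the gene tests. The identifiers of 11128 named spots were found in the reference gene table of assembly R64, and 0 symbols needed updating. The assembly was used for names and neighbours only. Spots of a gene were averaged, which gave 5539 genes, 5510 of them with 2 spots and 29 with 4 or 6. Spotted probes can bind near-identical copies, so values of the CUP1 copies, the aryl-alcohol dehydrogenase genes, paired ribosomal protein genes, histone gene copies, HXT6 and HXT7, and SSA3 and SSA4 are uncertain as to the copy.

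The log2 ratios were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over all 15 arrays, with a mean per time point and a gene-specific dye effect estimated from the 1 h arrays of both orientations. Values at 15 min, 30 min and 18 h were thus the mean of 3 arrays less that effect, and differences from 1 h took their size from the 3 arrays at 1 h with treated RNA in Cy5. The fit had 10 residual degrees of freedom and a prior of 5.41. Each time-point mean was tested against 0, and each time point against the one before it, giving 7 comparisons. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg within a comparison, two-sided), and errors of log2 ratios are limma standard errors. The dye effect passed the threshold in 0 genes (limma) and had a median of -0.05. Signal over background is not known from these values, and the number of arrays limits the precision.

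A set of 33 gene lists was fixed before the data were examined. Each list was tested with limma's camera, which compares a list with all other genes (preset inter-gene correlation of 0.01, two-sided, Benjamini-Hochberg over 231 tests), with camera using a correlation estimated for each list, and with fry. The fry test asks whether the genes of a list move, on balance, in one direction, and does not compare them with other genes. Members called are counted over all genes tested and "adjusted over the list alone". The genes named were set by a rule fixed beforehand. For each time point it took the 12 largest rises and 12 largest falls among called genes that moved the same way on all its arrays. For each difference between time points it took the 8 largest each way. Of each list described it took the 4 members with the smallest adjusted p, or all members of lists of at most 8. Some list members that the rule allows, aryl-alcohol dehydrogenases among them, are not named in the text.

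The fit and the list tests were tested on simulated arrays with the genes' own residual spread, independent noise and 200 of 5539 genes changed. At 1 h, 73.1% of genes changed by a log2 size of 1 and 100% of those changed by 2 were recovered. At 15 min, 30 min and 18 h, 29.9%, 25.4% and 20.9% of genes changed by 1 were recovered, and 88.1%, 80.6% and 85.1% of those changed by 2. For 18 h against 1 h, 13.4% and 77.6% were recovered. Of the calls in these simulations, 2.44% to 5.51% were false. A list of 20 genes raised by 1 was called in 7 of 7 comparisons by camera with either correlation and by fry. Of 224 unchanged lists, camera called 0 with either correlation and fry 1, between 15 and 30 min. The noise was independent between genes, so correlated lists were not simulated.

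Alternatives fixed beforehand were: no dye term; only the 1 h arrays with treated RNA in Cy5; no centring; arrays scaled to equal spread; the median of a gene's spots; robust empirical Bayes; only the arrays of the groups compared; the replicate number as a block; changes over 2-fold only; and leaving out each array. Alternatives added after seeing the data removed the dependence of each array's ratios on spot brightness by loess, left out the 2 arrays made another way, did both, or left out the dimmest tercile of genes. Spot brightness was the mean log2 of the smallest pair of whole numbers giving each ratio, centred per array, with its median taken over the 10 arrays with such ratios. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.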

Results

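Transcript levels in wild-type yeast were followed after 15 min, 30 min, 1 h and 18 h in 1.0 mM arsenite, As(III), a toxic trivalent form of arsenic, each time against untreated cells on the same slide. The 15 arrays (3, 3, 6 and 3 in order of time) measured 5539 named genes. Each value below is a log2 ratio of treated over untreated cells relative to the median gene, with its limma standard error. At 1 h it rests on 6 arrays. At 15 min, 30 min and 18 h it rests on 3 arrays, all with treated RNA in Cy5, less a dye effect estimated from the 6 arrays at 1 h, so the size of a difference from 1 h uses the 3 arrays with treated RNA in Cy5 there. Of 61 named values at 15 min, 30 min and 18 h, 59 were larger in size than the mean of their 3 arrays, which a fit without the dye term gives, and 16 lay outside the range of these arrays (4, 5 and 7 in order of time). In 15 of the 61 (1, 7 and 7) the fold differed by more than 1.5 times between the fits with and without the dye term. Pairs of 1 h arrays correlated across genes, which are not independent replicates, with r of 0.722 to 0.894, and the 3 pairs at 18 h with 0.447, 0.549 and 0.735. At 30 min, replicates 2 and 3 correlated with r = 0.927 and replicate 1 with them at 0.406 and 0.425. The 15 min arrays shared little, with r of -0.06, 0.22 and 0.23. Ratios also depended on spot brightness: the brightest minus the dimmest eighth of genes reached -1.84 on 15 min replicate 2 and -1.92 and -1.83 on 30 min replicates 2 and 3. As deposited, before centring, gene medians averaged 0.24 at 15 min, -0.34 at 30 min, -0.55 at 1 h and 0.46 at 18 h. List members other than those set by the rule for named genes (SUL2, GRX4, GPP1, GPP2, PGM1, LYS1, HOM6, CTR3, ZRT2, and HXT6 and GLO1 at 18 h) are named because few moved as they did, after their values were seen.

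**Figure D1:**
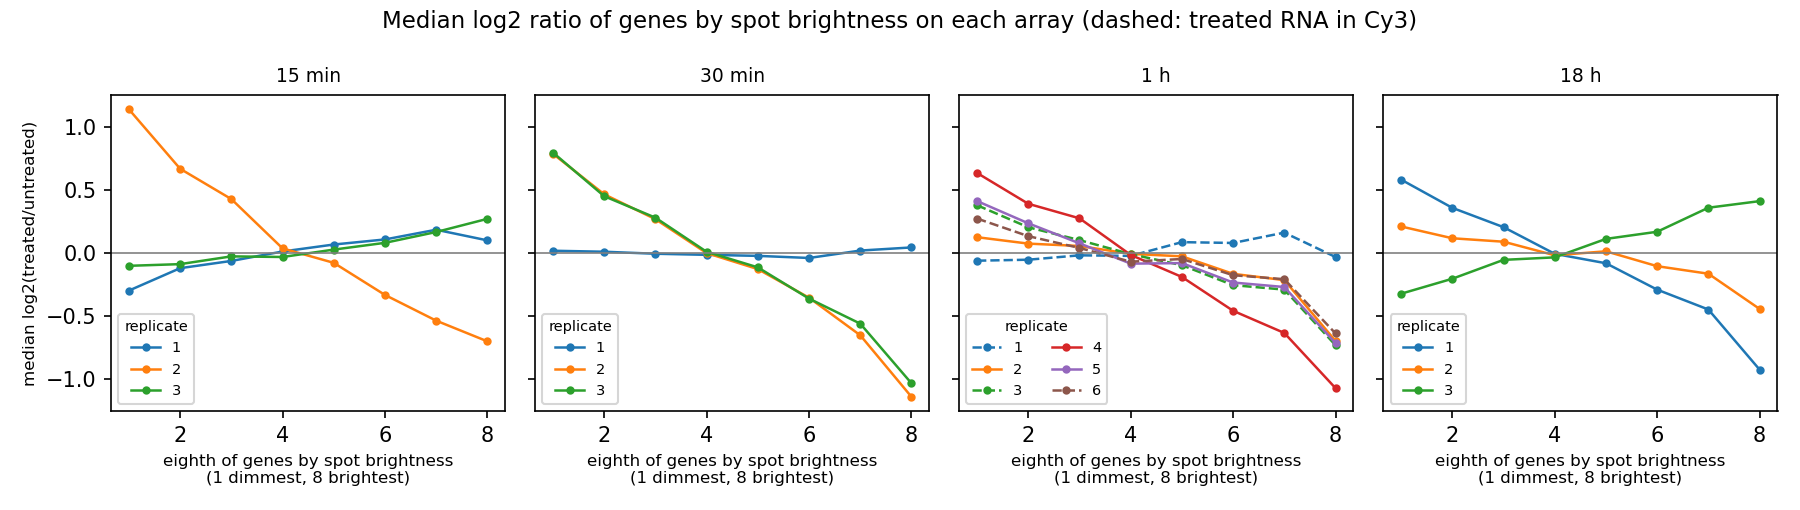
Median log2 ratio of treated over untreated cells (vertical axis) in eighths of genes ordered by spot brightness (horizontal axis, dimmest to brightest), 1 panel per time point and 1 line per array, dashed where treated RNA was in Cy3. The brightest minus the dimmest eighth was -1.92 on 30 min replicate 2 and 0.03 on 30 min replicate 1.

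After 15 min, SSA4, a stress-induced Hsp70 chaperone, rose 13.3-fold (log2 3.73 ± 0.55, adjusted p = 0.0031), and FES1, a nucleotide exchange factor of Hsp70, rose 8.73-fold (3.13 ± 0.38, adjusted p = 0.0029). The FES1 value lay above its 3 arrays (1.68 to 2.78) and was 2.28 without the dye term. The small heat shock protein gene HSP26 rose by 3.50 ± 0.67, HSP12 by 2.82 ± 0.39 and CUR1, which acts in the sorting of misfolded proteins, by 2.46. OYE3, an NADPH oxidoreductase, rose by 2.77 ± 0.36, the metallothionein copies CUP1-1 and CUP1-2 by 2.42 and 2.52, and RPN4, the transcription factor of proteasome genes, by 2.26 ± 0.47. TMA10 (3.41), ZPR1 (2.71) and LST8 (2.47) completed the largest rises. The histone H4 gene HHF2 was the 1 gene that fell (-1.72 ± 0.36, adjusted p = 0.036). In all, 37 genes rose and 1 fell (539 at an unadjusted p under 0.05).

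Of 30 heat shock and chaperone genes, 10 rose at 15 min and none fell (24 adjusted over the list alone), HSP10 by 1.93 among them. The list's camera adjusted p was 1.5e-29 (adjusted p = 0.180 with an estimated correlation). Of 22 genes of oxidative stress defence, OYE3 and the thioredoxin gene TRX2 (1.68 ± 0.31) rose (13 adjusted over the list alone), with a camera adjusted p of 2.2e-12 (adjusted p = 0.180 with an estimated correlation). Of 37 proteasome and ubiquitin genes, RPN4 and PRE1 (1.19 ± 0.26) rose (12 adjusted over the list alone), with a camera adjusted p of 6.3e-12 (adjusted p = 0.273 with an estimated correlation). Called members of the sulfate assimilation list numbered 0 of 26 by limma over all genes and 9 adjusted over the list alone, and of the 6 aryl-alcohol dehydrogenases 0 and 6. Their list medians were 0.64 and 1.35 (camera adjusted p = 2.0e-06 and 1.9e-06, adjusted p = 0.248 and 0.206 with an estimated correlation). The 132 ribosomal protein genes held 0 called genes on either count, with a median of -0.63 that stood at 0.15 without centring. The 66 ribosome biogenesis genes held 0 over all genes and 1 adjusted over the list alone, with a median of -0.54 that stood at 0.24 without centring. Camera gave these lists adjusted p = 3.3e-15 and 1.1e-14 (adjusted p = 0.459 and 0.251 with an estimated correlation). Arrays scaled to equal spread gave 4 genes higher and 1 lower, with FES1 the 1 gene named above still called, and with the brightness trend removed HSP26 stood at 3.42 ± 0.81 in place of 3.50 ± 0.67 and lost its call (adjusted p = 0.053) with the larger error. Leaving out 1 h replicate 1, 1 h replicate 4 or 15 min replicate 3 left 22, 24 and 13 higher genes, and HSP26, TMA10, RPN4 and HHF2 each lost the call without some 1 array. HHF2 also lost it in the arrays as deposited and in a fit of the 15 min arrays alone.

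After 30 min, HSP26 was 32.5-fold up (5.02 ± 0.67), HSP12 23.5-fold (4.55 ± 0.39) and OYE3 20.9-fold (4.39 ± 0.36). SSA4 rose by 3.65, RTC3 by 3.34, PRX1, a mitochondrial peroxiredoxin, by 3.17, TMA10 by 2.96, CTT1, the cytosolic catalase, by 2.95 and CUP1-1 by 2.91. SOL4 of the pentose phosphate pathway rose by 2.81, FRM2 by 2.77 and MET3, the ATP sulfurylase that opens sulfate assimilation, by 2.75. Of the 12 largest falls, 9 were ribosomal protein genes, from -3.29 (RPS0B) to -4.05 ± 0.84 (RPL3, adjusted p = 0.013). Without the dye term RPL3 stood at -3.48, RPS2 at -2.80 in place of -3.82 and RPS17A at -2.70 in place of -3.78, the last outside its arrays (-3.47 to -1.27). The other 3 were HNM1, the choline transporter (-3.70), ASC1, a protein bound to the small ribosomal subunit (-3.67), and GDH1, an NADP-dependent glutamate dehydrogenase (-3.20). HNM1, ASC1 and SOL4 stood at -2.76, -2.66 and 1.97 without the dye term. In all, 181 genes rose and 248 fell (1269 at an unadjusted p under 0.05).

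By list, 93 of 132 ribosomal protein genes fell at 30 min and none rose, with a median of -2.46 (122 adjusted over the list alone) and RPL37A, RPS18B and RPL6A at -2.31, -2.62 and -2.76. Ribosomal protein genes had a camera adjusted p of 6.8e-48 (adjusted p = 0.208 with an estimated correlation). Of 66 ribosome biogenesis genes 22 fell, among them NOP56 (-2.18) and DBP3 (-2.09), and 45 adjusted over the list alone (camera adjusted p = 6.3e-18, adjusted p = 0.227 with an estimated correlation). Both lists lay lower on replicates 2 and 3 than on replicate 1. Array medians were -0.47, -3.32 and -3.47 for ribosomal protein genes and -0.49, -1.43 and -1.67 for ribosome biogenesis. Heat shock genes (0.99, 1.15 and 1.05) and oxidative stress genes (0.97, 1.15 and 1.10) lay close together on the 3 arrays. Of the heat shock list 11 of 30 rose, and of the oxidative stress list 7 of 22 (19 and 16 adjusted over the list alone). Their camera adjusted p was 1.5e-14 and 3.4e-11 (adjusted p = 0.206 and 0.180 with an estimated correlation). Proteasome genes rose in 12 of 37 cases, PRE1 by 1.35 and RPN12 by 1.14 (26 adjusted over the list alone, camera adjusted p = 3.1e-13, adjusted p = 0.254 with an estimated correlation). Sulfate assimilation genes rose in 7 of 26 cases, with MET16 at 2.34 and MET14 at 2.03, and 5 of the 6 aryl-alcohol dehydrogenases rose while AAD4 stood at 1.21, not called (11 and 6 adjusted over the list alone). For these lists camera gave adjusted p = 3.2e-06 and 6.1e-07 (adjusted p = 0.251 and 0.180 with an estimated correlation). The 30 min counts rested on few arrays. Without replicates 1, 2 and 3 in turn, 566, 5 and 5 genes fell, and without replicates 2 and 3, 40 and 33 rose. Without 1 h replicates 2, 3 and 6, from which the dye effect is estimated in part, 94, 119 and 99 rose and 89, 99 and 81 fell. Scaled arrays gave 53 higher and 94 lower, the 30 min arrays alone 15 and 0, and arrays with treated RNA in Cy5 alone 208 and 568. Of the 24 genes named, 15 lost the call without replicate 2 or 3, all of the falls except RPL6B among them. With the 30 min arrays alone 18 lost it, HSP26, RTC3 and RPL6B among them. With scaled arrays 14 lost it, OYE3, SSA4 and RPL6B among them.

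**Figure D2:**
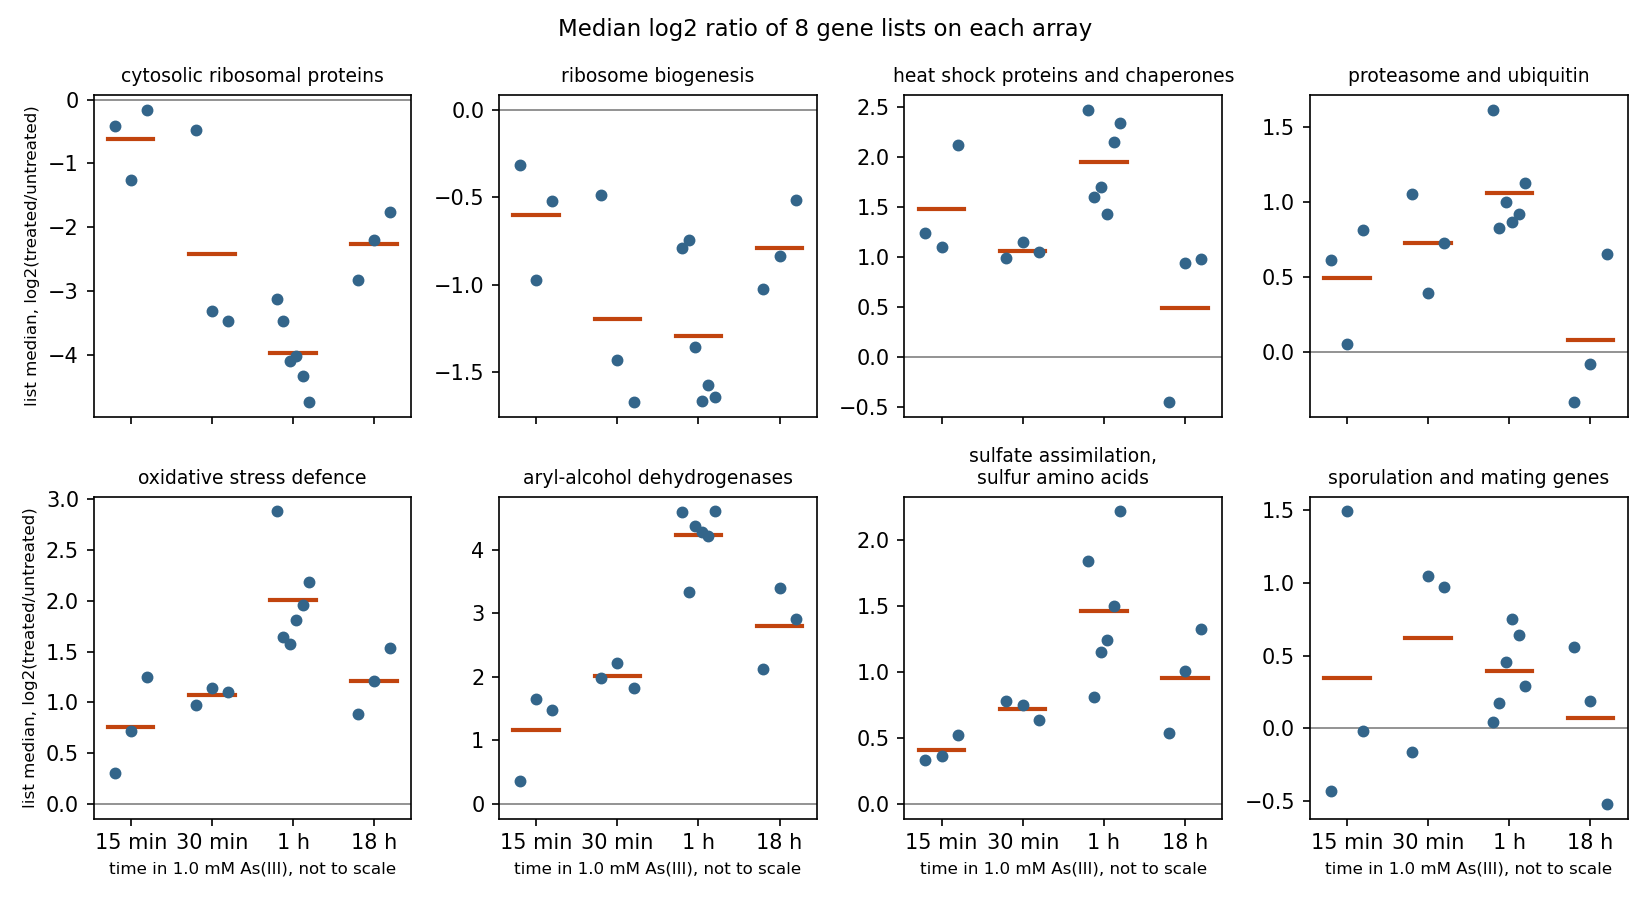
Median log2 ratio of treated over untreated cells in 8 gene lists (vertical axis) by time in arsenite (horizontal axis), 1 point per array and a red line at the mean of the arrays. Ribosomal protein genes lay between -3.13 and -4.75 on the 6 arrays at 1 h, and at -0.47 on 30 min replicate 1 against -3.32 and -3.47 on replicates 2 and 3.

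After 1 h, the largest rises were those of HSP26 (72.5-fold, 6.18 ± 0.39, adjusted p = 1.5e-08) and OYE3 (66.2-fold, 6.05 ± 0.21, adjusted p = 4.3e-11). GRE2, a methylglyoxal reductase, rose 45.2-fold (5.50 ± 0.42). HSP42, a second small heat shock protein, rose by 5.25, HSP12 by 5.18, SSA4 by 5.03, BTN2, a relative of CUR1 that also sorts misfolded proteins, by 4.99, and SSA3 by 4.77. AAD6 (4.57), AAD14 (4.51), AAD15 (4.44) and YML131W (4.55) rose as well. All 12 of the largest falls were ribosomal protein genes, from -4.57 (RPL13B) to -4.95 ± 0.40 (RPS0B) and -4.97 ± 0.49 (RPL3). In all, 946 genes rose and 1251 fell (2628 at an unadjusted p under 0.05), 378 and 676 of them by more than 2-fold. The share of higher genes depended on centring: as deposited, 160 genes were higher and 1308 lower. The 1 h arrays with treated RNA in Cy5 alone gave 422 higher and 894 lower. All 24 genes named kept their calls in the alternatives run.

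Of 132 ribosomal protein genes, 126 fell at 1 h and none rose, with a median of -3.95 (128 adjusted over the list alone, camera adjusted p = 2.8e-51, adjusted p = 0.206 with an estimated correlation). Ribosome biogenesis genes fell in 59 of 66 cases, among them NOP58 (-3.35) and NOP56 (-3.28), partners in the box C/D particle. RNA polymerase I and III genes fell in 12 of 20, RPA135 among them at -2.45 (61 and 13 of these lists adjusted over the list alone). Their camera adjusted p was 7.6e-17 and 0.00024 (adjusted p = 0.227 and 0.208 with an estimated correlation). All 30 heat shock and chaperone genes rose (30 adjusted over the list alone), with a median of 1.86 and HSP31 at 3.88. Of the oxidative stress genes 19 of 22 rose (20 adjusted over the list alone), with TRX2 at 2.94 and the methionine sulfoxide reductase gene MXR1 at 3.02. Heat shock and oxidative stress lists had camera adjusted p = 2.5e-20 and 2.0e-14 (adjusted p = 0.180 for both with an estimated correlation). Proteasome and ubiquitin genes rose in 31 of 37 cases and none fell, with RPN4 at 3.03 and RPT5 at 1.76 (33 higher and 1 lower adjusted over the list alone). Camera gave them an adjusted p of 1.1e-12 (adjusted p = 0.257 with an estimated correlation). All 6 aryl-alcohol dehydrogenases rose, with a median of 4.41 (6 adjusted over the list alone, camera adjusted p = 1.7e-08, adjusted p = 0.180 with an estimated correlation).

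Of 26 sulfate assimilation and sulfur amino acid genes, 17 rose at 1 h, MET3 by 4.07 ± 0.24, MET14 by 3.69 ± 0.21 and MET16 by 3.51, while 1, the sulfate permease gene SUL2, stood at -0.99 and fell (18 and 1 adjusted over the list alone). Sulfur genes had a camera adjusted p of 7.4e-09 (adjusted p = 0.206 with an estimated correlation). Of 21 glutathione genes 11 rose, with GSH1, the first enzyme of glutathione synthesis, at 2.21 ± 0.21, GRX2 at 2.03, DUG2 at 2.75 and GLO1 at 2.05. The glutaredoxin gene GRX4 (-0.42) and YCF1 fell (15 higher and 2 lower adjusted over the list alone). Glutathione genes had a camera adjusted p of 4.7e-05 (adjusted p = 0.180 with an estimated correlation). Of the 7 genes of arsenic transport and detoxification, the arsenite exporter gene ARR3 rose by 1.29 ± 0.31, the arsenate reductase gene ARR2 by 1.03 ± 0.27 and RGC1 by 0.77 ± 0.18. YCF1, a vacuolar transporter of glutathione conjugates, fell (-1.03 ± 0.21). ARR1, the activator of both ARR genes, stood at -0.11, the glycerol channel gene FPS1 at 0.25 and ASK10 at 0.29, none of them called (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.274). Of 12 metallothionein and metal transporter genes, CUP1-1 (3.59), CUP1-2 (3.51) and CTR3 (0.49) rose, and ZRT1 (-2.12), ZRT2 (-1.01) and ZRC1 (-1.46) fell (3 and 3 adjusted over the list alone). That list had a median of -0.31, a mean of 0.15 and a camera direction of lower (adjusted p = 0.928).

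Metabolic genes moved in both directions at 1 h. Amino acid synthesis genes other than those of sulfur fell in 30 of 44 cases, with the branched-chain enzyme gene ILV5 at -3.85 and ARO4 at -2.34, and LYS1 (1.42) and HOM6 (0.70) rose (30 lower and 3 higher adjusted over the list alone). Amino acid genes had a camera adjusted p of 1.7e-06 (adjusted p = 0.463 with an estimated correlation). Glycolysis and fermentation genes fell in 9 of 19, among them CDC19, the pyruvate kinase (-2.83), and PFK2 (-2.26), as did 9 adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.664 with an estimated correlation). Osmotic stress and glycerol genes rose in 13 of 19, ALD3 by 3.83 and GRE3 by 2.66, while GPP1 (-3.22) and GPP2 (-1.70), the glycerol phosphatases, fell (13 and 2 adjusted over the list alone). Osmotic genes had a camera adjusted p of 9.3e-05 (adjusted p = 0.206 with an estimated correlation). Trehalose and glycogen genes rose in 10 of 17, TSL1 by 2.03, and GLG1 (-0.98) and PGM1 (-0.68) fell (10 and 2 adjusted over the list alone). The trehalose list median of 0.54 stood at -0.01 without centring, and its camera adjusted p was 0.00892 (adjusted p = 0.346 with an estimated correlation). Stationary phase genes rose in 11 of 14, YGP1 by 2.99 (11 adjusted over the list alone, camera adjusted p = 9.3e-07, adjusted p = 0.206 with an estimated correlation).

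**Figure D3:**
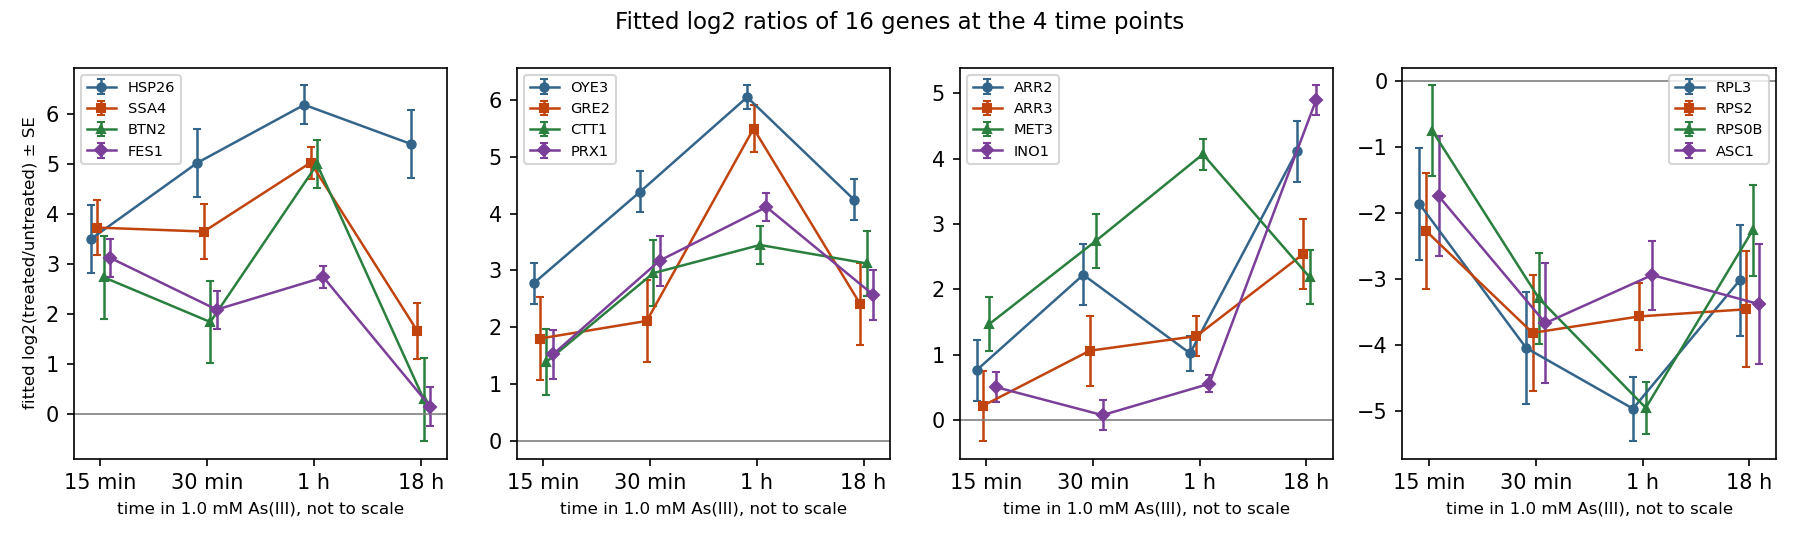
Fitted log2 ratio of treated over untreated cells (vertical axis) by time in arsenite (horizontal axis) for 16 genes in 4 panels, after the dye effect was taken off, with bars of 1 limma standard error. HSP26 stood at 3.50, 5.02, 6.18 and 5.40 at 15 min, 30 min, 1 h and 18 h, and INO1 at 0.51, 0.08, 0.56 and 4.89.

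After 18 h, GRE1, a hydrophilin, was 42.5-fold up (5.41 ± 0.79), HSP26 42.1-fold (5.40 ± 0.67) and INO1, the inositol-3-phosphate synthase, 29.7-fold (4.89 ± 0.23, adjusted p = 3.7e-09). HSP12 rose by 4.38, OYE3 by 4.25, GPT2, an acyltransferase of glycerolipid synthesis, by 4.10, DDR2 by 3.92, HSP30 by 3.85, FRM2 by 3.74, SPI1 by 3.71 and AAD3 by 3.68. HSP30 and SPI1 lay above their 3 arrays (2.41 to 3.66 and 2.40 to 3.47) and were 3.21 and 3.08 without the dye term. ARR2 rose 17.3-fold (4.11 ± 0.47, adjusted p = 0.00013) and ARR3 by 2.54 ± 0.54. The rise of ARR2 had been called at 30 min too (2.22 ± 0.47, limma adjusted p = 0.013). That value lay above the 1.03 of 1 h, but the difference between these 2 times did not pass. ARR1 stood at -0.49, FPS1 at 0.11, ASK10 at 0.76, RGC1 at 1.01 and YCF1 at -1.06, none of them called. The arsenic list thus held 2 of 7 higher (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0565, fry adjusted p = 0.0018). Of the 12 largest falls, 10 were ribosomal protein genes, from -2.98 (RPL16A) to -3.46 ± 0.88 (RPS2). The RPS2 value lay below its 3 arrays (-3.29 to -1.66) and was -2.44 without the dye term, and RPS17A stood at -3.36 against arrays of -2.75 to -1.93 and at -2.28 without it. ASC1 (-3.38) and SFT1, a SNARE of the Golgi (-2.95), fell with them. In all, 295 genes rose and 175 fell (1233 at an unadjusted p under 0.05).

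Ribosomal protein genes fell in 90 of 132 cases at 18 h, with a median of -2.28 (122 adjusted over the list alone, camera adjusted p = 4.4e-49, adjusted p = 0.208 with an estimated correlation). Ribosome biogenesis genes fell in 2 of 66, GAR1 (-1.45) and NHP2 (-1.74), with a median of -0.72 that stood at 0.28 without centring (1 adjusted over the list alone, camera adjusted p = 8.2e-12, adjusted p = 0.285 with an estimated correlation). Oxidative stress genes rose in 12 of 22, SOD2 by 2.25 and PRX1 by 2.57, sulfur genes in 13 of 26, the sulfate permease gene SUL1 by 2.67 ± 0.35, and all 6 aryl-alcohol dehydrogenases (15, 15 and 6 adjusted over the list alone). These 3 lists had camera adjusted p = 8.0e-12, 1.2e-09 and 1.5e-09 (adjusted p = 0.180, 0.206 and 0.180 with an estimated correlation). Osmotic stress genes rose in 11 of 19 and stationary phase genes in 10 of 14, with SPG5 at 2.79 and YGP1 at 3.23 (14 and 10 adjusted over the list alone). Their camera adjusted p was 3.4e-08 and 1.4e-11 (adjusted p = 0.180 for both with an estimated correlation). Trehalose and glycogen genes rose in 7 of 17, GAC1 by 2.12 and PGM2 by 2.03 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.4e-05, adjusted p = 0.208 with an estimated correlation). Of 21 glutathione genes, GTT1 (1.88), GSH1 (1.75), DUG3 (1.63), GRX2 (1.56) and GLO1 (1.37) rose (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00521, adjusted p = 0.257 with an estimated correlation). Heat shock genes rose in 7 of 30, HSP31 by 3.45, with array medians of -0.45, 0.94 and 0.98 (8 adjusted over the list alone). Heat shock genes had a camera adjusted p of 7.4e-06 (adjusted p = 0.357 with an estimated correlation). Of 37 proteasome genes RPN4 (1.63) and the polyubiquitin gene UBI4 (1.50) rose (1 adjusted over the list alone, camera adjusted p = 0.0751). Without centring, 348 genes were higher and 8 lower, and RPL3, RPL16A, RPS1B and SFT1 were no longer called. Leaving out replicate 3 left 147 higher genes. Without replicates 1, 2 and 3 in turn, 37, 59 and 80 genes were lower, without 1 h replicates 2, 3 and 6, 79, 85 and 64, and without 30 min replicate 1, 265. Of the 24 genes named, 10 lost the call without some 1 array and 10 in scaled arrays, which gave 151 higher and 69 lower. The arrays with treated RNA in Cy5 alone gave 379 and 347, with ASC1, RPL17B and RPS2 lost, and a fit without the dye term 440 and 463, with ASC1 (-2.37) lost.

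Successive time points were compared by testing the difference itself. Between 15 and 30 min, 0 genes passed (limma; 383 at an unadjusted p under 0.05), and between 30 min and 1 h also 0 (limma; 286 at an unadjusted p under 0.05). Without 15 min replicate 2, 10 genes were higher and 1 lower at 30 than at 15 min, and without 30 min replicate 1, 10 were higher and 203 lower. Without 1 h replicate 2, 1 gene was higher at 1 h than at 30 min. The 132 ribosomal protein genes had median differences of -1.76 between 15 and 30 min and -1.46 between 30 min and 1 h, with 0 called by limma over all genes and 59 and 9 lower adjusted over the list alone. Camera adjusted p was 2.3e-41 and 6.9e-35 for these differences (adjusted p = 0.227 and 0.254 with an estimated correlation). The 6 aryl-alcohol dehydrogenases differed by a median of 2.00 between 30 min and 1 h, with 0 called over all genes and 6 adjusted over the list alone (camera adjusted p = 1.1e-14, adjusted p = 0.180 with an estimated correlation, fry adjusted p = 0.0066).

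Between 1 h and 18 h, 58 genes were higher at 18 h and 20 lower (752 at an unadjusted p under 0.05). INO1 was 20.2-fold higher at 18 h than at 1 h (4.33 ± 0.26, adjusted p = 1.9e-07). The polyamine transporter gene TPO2 differed by 4.06, the zinc transporter gene ZRT1 by 4.01, and the hexose transporter genes HXT3 and HXT7 by 3.84 and 3.67. TYE7, a regulator of glycolytic genes, differed by 3.75, the glutamine synthetase gene GLN1 by 3.50 and PMA1, the plasma membrane proton pump, by 3.49. Against untreated cells, ZRT1, HXT3, TYE7, GLN1 and PMA1 were lower at 1 h (-2.12, -2.39, -2.40, -3.16 and -3.07). They were not called at 18 h (1.89, 1.45, 1.34, 0.34 and 0.41). INO1, TPO2 and HXT7 were called higher than untreated at 18 h (4.89, 2.80 and 2.52). Lower at 18 h were BTN2 (-4.69 ± 0.95), SSA4 (-3.36 ± 0.64), the cyclophilin gene CPR6 (-2.83), FES1 (-2.58), CUP1-1 (-2.54), YHR054C (-2.52), CUP1-2 (-2.47) and DUG2 (-2.36). By systematic names, YHR054C lies between CUP1-1 (YHR053C) and CUP1-2 (YHR055C), so the values of these neighbours may not be independent. ARR2 was higher at 18 h by 3.09 ± 0.54 (adjusted p = 0.013), and the difference of ARR3 did not pass (adjusted p = 0.39).

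Heat shock genes were lower at 18 h than at 1 h in 6 of 30 cases, SIS1 among them (-2.23 ± 0.35), with a median difference of -1.26 that stood at 0.29 without centring (15 adjusted over the list alone). Camera gave this difference an adjusted p of 9.8e-19 (adjusted p = 0.180 with an estimated correlation) and fry one of 0.014. Proteasome genes were lower in 2 of 37, RPN11 (-1.56) and RPN5 (-1.60), and oxidative stress genes in 2 of 22, MXR1 (-1.86) and OYE3 (-1.80), with 9 and 7 adjusted over the list alone. Their medians of -0.67 and -0.65 stood at 0.87 and 0.90 without centring (camera adjusted p = 2.5e-14 and 1.7e-06, adjusted p = 0.248 for both with an estimated correlation). Amino acid synthesis genes were higher in 3 of 44, GCN4, their transcriptional activator, by 3.18, LYS12 by 2.43 and LYS21 by 2.12 (18 adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.413 with an estimated correlation). Of 17 hexose transporter genes, HXT4 (2.22), HXT1 (2.21) and HXT6 (3.19) were higher with HXT3 and HXT7 (5 adjusted over the list alone, camera adjusted p = 0.0578). Ribosomal protein genes had a median difference of 1.61 with 1 called, RPL37A at 1.91 (39 adjusted over the list alone, camera adjusted p = 6.2e-20, adjusted p = 0.389 with an estimated correlation). The balance depended on scale: without centring 1014 genes were higher and 1 lower, and with scaled arrays 55 and 1. Of the 16 genes named, 7 and 8 were then no longer called, CPR6, CUP1-1, CUP1-2, DUG2, FES1 and SSA4 in both. Without 1 h replicate 4, 1 h replicate 5, 30 min replicate 1 or 18 h replicate 3, 11, 14, 139 and 8 genes were higher and 5, 2, 34 and 1 lower, and without 18 h replicate 1, 6 were lower. Arrays with treated RNA in Cy5 alone, which give the same sizes of difference with fewer arrays behind the error, gave 41 higher and 13 lower, with CPR6, DUG2 and PMA1 no longer called. Of the 16 named genes, INO1 alone kept its call without any 1 array. Sizes moved as well: TPO2 stood at 3.00 and 4.47 without 1 h replicates 4 and 5. PMA1 stood at 2.53 without 18 h replicate 3 and BTN2 at -3.615 without 18 h replicate 1.

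Over the 231 tests of 33 lists in 7 comparisons, camera called 66 higher and 46 lower at its preset correlation. With a correlation estimated for each list, 0 of the 112 calls held (limma's camera; lowest adjusted p = 0.180; 49 of 231 at an unadjusted p under 0.05). By fry, 67 lists were called, 57 of them also by camera.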

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

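The tests of spot brightness, dye, how an array was made, scale and glucose in this part were chosen only after the result was seen, while those of other splits of the arrays and of a smaller response at 15 min were set before.

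The arrays at 15 min shared little: pairs correlated with r of -0.06, 0.22 and 0.23 across genes, which are not independent replicates, against 0.722 to 0.894 at 1 h. Removing the dependence on spot brightness raised the highest pair at 15 min to 0.449, below the lowest 1 h pair treated alike (0.778), which argues against that trend as the whole cause. Replicate 1, made another way, was not the whole cause either, since replicates 2 and 3 correlated with r = 0.220. A smaller response measured as precisely as at 1 h stays open: with the trend removed, the variance shared by replicates 2 and 3, the 1 pair left without replicate 1, was 0.205 against 0.937 at 1 h, and the part not shared 0.286 against 0.207, or 1.38 times, close to the range of 1 h pairs (0.133 to 0.270). Samples that differed from one another at 15 min also remain open and were not tested.

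Ribosomal protein genes were lower on all 6 arrays at 1 h and on 30 min replicates 2 and 3, but hardly on 30 min replicate 1 (median -0.47). Against equally bright genes the list still lay at -3.10 or lower on every 1 h array and at -2.52 or lower on 30 min replicates 2 and 3. With the trend removed its median was at -2.67 or lower at 1 h but shrank to -1.78 and -2.09 on 30 min replicates 2 and 3 (from -3.32 and -3.47), and its highest median as measured on a 1 h array of either dye orientation was -3.13, which argues against brightness at both times, and against dye at 1 h, as the whole cause. The heat shock median of 30 min replicate 1 was 0.901 times the mean of the other 2 arrays. The SD over genes of that replicate was 0.489, however, against 1.10 and 1.12 on replicates 2 and 3. A single list median therefore cannot decide on a smaller scale of its values. That ribosomal protein transcripts fell in arsenite may hold as a biological hypothesis, found and tested on the same data. Why 30 min replicate 1 differed stays open (an earlier stage of the response is one possibility, not tested), and no label says how the 30 min samples differed.

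Between 18 h and 1 h, 58 genes were higher and 20 lower, by the test of the difference itself. The higher genes named were INO1 (4.33), TPO2 (4.06), ZRT1 (4.01), HXT3 (3.84), TYE7 (3.75), HXT7 (3.67), GLN1 (3.50) and PMA1 (3.49). The lower ones were BTN2 (-4.69), SSA4 (-3.36), CPR6 (-2.83), FES1 (-2.58), CUP1-1 (-2.54), YHR054C (-2.52), CUP1-2 (-2.47) and DUG2 (-2.36). Of the higher ones, ZRT1, HXT3, TYE7, GLN1 and PMA1 were called lower than untreated at 1 h and were not called at 18 h. With the brightness trend removed all 16 stayed past the threshold, which argues against brightness as the whole cause for these 16 alone. They were picked as the largest differences, so this says little about the other genes called. Over all genes, 147 were then higher and 102 lower. Of 84 splits of the 9 arrays 2 gave as many genes (78 in the real split and 78 in the highest other), but these 2 give the same difference under the dye term, and the 20 splits that keep the dye orientation (0 genes by limma in the highest apart from these 2) are too few for a share under 0.05. Time in arsenite, the age of the culture and the untreated control used at 18 h stay open and may each contribute. A treated culture that alone had run out of glucose also stays open. The median of glucose-repressed genes, at most 0.278 on an 18 h array with an SD over members of 0.517 to 1.17, decides nothing. Stationary phase genes rose in 10 of 14 cases at 18 h but in most cases at 1 h too, so their rise does not set 18 h apart. Of the 16 named genes 15, all but INO1, lost the call without some 1 array, with 8 higher and 1 lower genes left without 18 h replicate 3.

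Other splits of the arrays, made by turning the sign of some arrays or regrouping them, were counted for each comparison. At 1 h, 1 of 32 splits (the real one) gave 2197 genes and the highest other 952, so turning the signs of these arrays at random rarely gives as many. Turned signs cannot speak to a difference between samples that all 1 h arrays share, as they would if replicates were technical. At 15 min, 30 min and 18 h, 1 of 4 splits each gave 38, 429 and 470 genes and the highest other 1, 0 and 0, with too few splits for a share under 0.05. Between 15 and 30 min the real count was 0 (limma), so all 10 of 10 splits gave as many and the count says nothing about chance. With 1711 genes, 1 of them gave the highest other count, 15 min replicates 1 and 3 with 30 min replicate 1 against 15 min replicate 2 with 30 min replicates 2 and 3. The last 3 are the arrays with the steepest brightness trends in that split (-1.84, -1.92 and -1.83, against 0.40, 0.37 and 0.03), and 15 min replicate 2 correlated across genes, which are not independent replicates, with 30 min replicates 2 and 3 at r = 0.838 and 0.823. Whether that split reflects the samples or the brightness trend was not tested. Between 30 min and 1 h the real count was also 0 (limma), so that 84 of 84 splits gave as many, with 76 in the highest, and this too says nothing about chance.

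A single array stood apart in 4 of 57 values tested at 1 h, where chance gives about 5% of groups. On replicate 2, YML131W was at 3.11 and the aryl-alcohol dehydrogenase median at 3.33, both lower than on the other arrays. On replicate 1, the median of cytosolic chaperonin and prefoldin genes was at 0.592 and that of actin and tubulin genes at 0.481, both higher than on the others.

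Spots without a gene name, left out of the gene tests, were tested apart at 1 h. Of 959 pairs of such spots, 136 were higher and 37 lower, 18.0% in all against 39.7% of named genes, with a median log2 ratio of 0.36. They were dim, with a median brightness of -0.67 against 0.14 for named genes. The dimmest eighth of named genes had medians of -0.06 on 1 h replicate 1 and of 0.12 to 0.63 on the other 1 h arrays. Whether the unnamed spots changed or share this dependence on brightness was not tested.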

How the results depend on the processing

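The alternatives that removed the brightness trend, left out the 2 arrays made another way (15 min replicate 1 and 30 min replicate 1), did both or left out the dimmest tercile were chosen after seeing the data. Filters for missing values were not run, because no value was missing. Of 101 results for named genes, 0 reversed and 38 kept their call under every alternative run for them (4 of the 101 were not run without the dimmest tercile). Calls were lost by 44 with scaled arrays, 19 with only the arrays compared, 12 as deposited, 6 with treated RNA in Cy5 only, 1 without the dye term, 1 with the trend removed, and in 146 cases (1369 kept) where 1 array was left out. Of 93 results for lists, camera's direction, which is relative to other genes, reversed in 1: glycolysis and fermentation genes at 30 min, with a median of -0.73, stood at 0.046 with the trend removed and the 2 arrays left out. The sign of the median itself also turned in 22 of the 93 as deposited, where shifts of whole arrays enter, and in 1 (iron uptake at 15 min, -0.20 to 0.041) without 1 h replicate 6. List calls were lost by 93 with an estimated correlation, 37 by fry, 12 without dim genes, 7 with both corrections, 6 with the trend removed, 6 as deposited, 4 with scaled arrays, 3 with only the arrays compared, 3 with Cy5 only, 2 without the dye term, 1 without the 2 arrays, and in 43 cases where 1 array was left out. Signal over background, which would limit dim spots, is not known.

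Counts are given as higher and lower where they moved by over 1.5 times, and the cause was not tested except where fewer arrays or a stricter threshold entered. Without the dye term, 4 were lower at 15 min, 276 and 702 moved at 30 min, 463 were lower at 18 h, 21 and 5 differed between 30 min and 1 h, and 164 and 114 between 1 h and 18 h. With treated RNA in Cy5 only, the lower counts were 2, 568 and 347 at 15 min, 30 min and 18 h and 13 between 1 h and 18 h, and 422 were higher at 1 h. As deposited, 0 were lower at 15 min (limma), 34 and 67 moved at 30 min, 160 were higher at 1 h, 8 lower at 18 h, and 1014 and 1 differed between 1 h and 18 h. Scaled, 4 were higher at 15 min, 53 and 94 moved at 30 min, 151 and 69 at 18 h, and 1 was lower at 18 h than at 1 h. With only the arrays compared, 15 and 0 moved at 15 min and at 30 min, 346 were lower at 18 h, 1 was higher at 1 h than at 30 min, and 119 and 35 differed between 1 h and 18 h. Over 2-fold, 378 and 676 moved at 1 h. With the trend removed, 56 and 7 moved at 15 min, 381 were higher at 30 min, 508 and 330 moved at 18 h, and 147 and 102 differed between 1 h and 18 h. Without the 2 arrays, 65 and 6 moved at 15 min, 283 and 619 at 30 min, 286 were lower at 18 h, 4 and 101 differed between 15 and 30 min, 1 was higher at 1 h than at 30 min, and 152 and 42 differed between 1 h and 18 h. With both, 143 and 43 moved at 15 min, 541 and 607 at 30 min and 608 and 436 at 18 h, 5 and 4 differed between 15 and 30 min, 1 and 1 between 30 min and 1 h, and 221 and 152 between 1 h and 18 h. Without the dimmest tercile, 3 were lower at 15 min. Against 112 list calls, fry made 67 and camera with an estimated correlation 0 (49 at an unadjusted p under 0.05).

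Leaving out each array in turn gave 13 to 45 higher and 0 to 6 lower genes at 15 min, 33 to 239 and 5 to 566 at 30 min, 724 to 1071 and 1017 to 1303 at 1 h, and 147 to 338 and 37 to 265 at 18 h. It gave 0 to 10 and 0 to 203 between 15 and 30 min, 0 to 1 and 0 to 0 between 30 min and 1 h (limma), 8 to 139 and 1 to 34 between 1 h and 18 h, and 108 to 119 list calls.

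Replicate numbers did not pair the samples throughout: of 18 pairs with the same number 6 had a correlation of deviations over 0.1 (-0.549 to 0.635), and 6 of 12 arrays matched their own number best. How many would match by chance was not computed. Between 15 and 30 min, the correlation was 0.575 and 0.635 for replicates 1 and 2 but -0.322 for replicate 3. With the replicate number as a block (consensus correlation -0.053), 40 and 1 moved at 15 min, 180 and 239 at 30 min, 940 and 1252 at 1 h and 293 and 162 at 18 h, with 0 and 0 between 15 and 30 min and between 30 min and 1 h (limma) and 62 and 20 between 1 h and 18 h. No call of a named gene was lost under the block.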

Other observations

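The 2 hypotheses and their tests at the end of this part, on RPN4 and on the neighbours of the ARR genes, were set before their results were seen, and the list members LSC2, FRE6, RNR1, PHO89, GIT1, GSC2 and YPS3 were named after their values were seen. Iron uptake genes fell in 12 of 26 cases at 1 h, among them the oxidase and permease of high-affinity uptake, FET3 (-3.98 ± 0.45) and FTR1 (-3.35), and FIT2 (-2.89), while FRE6 (0.85) rose (12 and 1 adjusted over the list alone). The camera adjusted p was 0.00379 (adjusted p = 0.562 with an estimated correlation), with array medians from -0.11 to -1.57. Ergosterol synthesis genes fell in 16 of 23, with ERG3 at -2.45 and ERG6 at -2.05 (16 adjusted over the list alone, camera adjusted p = 8.4e-05, adjusted p = 0.266 with an estimated correlation). Histone genes fell in 10 of 10, HTA1 (-2.52) furthest of those named (10 adjusted over the list alone, camera adjusted p = 9.2e-05, adjusted p = 0.330 with an estimated correlation). Phosphate regulon genes fell in 10 of 16 at 1 h, the transporter gene PHO84 among them (-1.83), and PHO89 (0.69) and GIT1 (0.62) rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.0203, adjusted p = 0.301 with an estimated correlation). PHO84 (1.48) and PHM8 (2.22) rose at 18 h and differed from 1 h by 3.31 and 2.18 (list camera adjusted p = 6.2e-05, adjusted p = 0.180 with an estimated correlation, 4 adjusted over the list alone). Autophagy genes rose in 8 of 15 at 1 h, APE1 by 2.00 and the kinase gene ATG1 by 1.43 (10 adjusted over the list alone, camera adjusted p = 0.00031, adjusted p = 0.206 with an estimated correlation), with a median of 0.53 that stood at -0.03 without centring. Of 10 DNA damage genes 6 rose at 1 h, DDI1 by 2.67 and the ribonucleotide reductase genes RNR4 and RNR2 by 2.42 and 2.01. RNR1, a subunit of the same enzyme, fell (-1.35), which gave 6 and 1 also adjusted over the list alone (camera adjusted p = 0.00787, adjusted p = 0.206 with an estimated correlation). Of 14 cell wall genes, PST1 (2.78), SED1 (2.63), PIR3 (2.35), GSC2 (1.67) and YPS3 (1.51) rose at 18 h and CWP1 (-2.46) fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00472, adjusted p = 0.371 with an estimated correlation).

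Central metabolism split within lists. Of 11 citric acid cycle genes, IDH2 (-2.46), IDH1 (-1.94), ACO1 (-1.56) and LSC2 (-1.26) fell at 1 h and MDH1 (0.65) rose (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.302, fry adjusted p = 0.033). Of 11 pentose phosphate genes 4 rose at 1 h, NQM1 by 2.42 and ZWF1, which opens the pathway, by 1.68, and 4 fell, TKL1 (-2.54) and RKI1 (-2.44) among them (4 and 6 adjusted over the list alone, camera adjusted p = 0.906). Of 17 hexose transporter genes at 1 h 4 rose, HXT5 by 1.46, and 5 fell, HXT3 among them (-2.39), with a median of 0.41, a mean of -0.05 and a camera adjusted p of 0.735 (5 and 7 adjusted over the list alone). Respiratory chain genes rose in 8 of 36, the cytochrome c isoform gene CYC7 by 2.43, and fell in 5, QCR6 among them (-1.61), with 8 and 5 adjusted over the list alone (camera adjusted p = 0.302). Glucose-repressed and gluconeogenic genes rose in 3 of 17, ALD4 by 2.73, and fell in 3, ADH2 among them (-2.22), with 3 and 3 adjusted over the list alone (camera adjusted p = 0.262). Of 65 genes listed by name pattern as mitochondrial ribosomal proteins, 4 rose and 8 fell, MRPL51 among the latter (-0.82). MRP8, which rose by 1.89, is in that list by its name alone. Adjusted over the list alone, 2 rose and 7 fell (camera adjusted p = 0.761). Cell cycle genes fell in 6 of 23, the G1 cyclin gene CLN3 among them (-1.69), with 6 adjusted over the list alone (camera adjusted p = 0.0766, fry adjusted p = 0.00096). Of 15 chaperonin and prefoldin genes CCT2 (1.08) rose and PFD1 (-0.62) fell (camera adjusted p = 0.792), and of 15 actin and tubulin genes CAP1 (1.21) rose and TUB4 (-0.54) fell (camera adjusted p = 0.852). Sporulation and mating genes, mostly silent in growing cells, rose in 2 of 18 and fell in 3 at 1 h (camera adjusted p = 0.298), but their median was 1.49 on 15 min replicate 2 and 1.05 and 0.98 on 30 min replicates 2 and 3, the arrays with the steepest brightness trend.

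A first hypothesis was that RPN4, which activates proteasome genes, may lead its targets, so that its excess over them would be higher at 15 min than at 1 h. RPN4 minus the median of the other 36 list members was 1.66 ± 0.361 (SD, n = 3) at 15 min and 1.99 ± 0.375 (SD, n = 6) at 1 h. The difference of -0.34 went against the hypothesis but lay within the spread (exact two-sided permutation test, p = 0.226 over 84 splits), so this test does not decide it. The test left out 30 min, where RPN4 stood at 0.61 ± 0.47 and was not called (limma adjusted p = 0.447). Array medians of the proteasome list were 1.05, 0.39 and 0.72 at that time. Between 15 and 30 min and between 30 min and 1 h, 0 genes passed (limma), so a dip of RPN4 at 30 min was not shown.

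A second hypothesis was that the rise of ARR2 and ARR3 at 18 h may belong to a change of their whole chromosome end. The 10 nearest measured genes had a median of 0.689 at 18 h, from -0.64 (RPC82) to 1.46 ± 0.41 (AQY1, adjusted p = 0.039), and AQY1 was the 1 of them called. ARR1 was left out of these 10 as an ARR gene, and it stood below 0 at 18 h and was not called. The neighbours lay below ARR2 (4.11) and ARR3 (2.54), but their median was above 0 with members on both sides. A smaller shift of the neighbourhood thus cannot be told apart from a change of ARR2 and ARR3 alone.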
